A study of Mus musculus with 6 samples.

How the data were processed

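Small RNAs of dorsal skin from female BALB/c mice were measured on 6 Agilent arrays of 1 colour (Cy3), 3 from vehicle-treated controls and 3 from mice treated with 2,4-dinitrochlorobenzene (DNCB), a hapten that sensitises skin and is used to induce a dermatitis resembling atopic dermatitis. Per the labels' protocols, 100 ng of total RNA per sample was dephosphorylated at its 3' ends with T4 polynucleotide kinase and end-labelled with pCp-Cy3 by T4 RNA ligase. Samples were grouped by the treatment in their labels and carry the numbers of their titles, 3, 5 and 6 in each group. The labels describe 6 mice in each group and do not say whether each array holds the RNA of 1 mouse, so that p-values measure the spread between these 6 samples.

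The deposited values are spot intensities on a linear scale. Per the file headers, Agilent Feature Extraction 11.0.1.1 subtracted a spatially detrended background within each array and no scaling between arrays was applied by the authors to these intensities. Per the file headers, the same software set the other values used here, which are 0 or 1 flags for each spot (well above background, positive and significant, saturated, outlier). Median spot and local background intensities, also deposited, are not corrected. Any further step the authors took is not given in the sources used here.

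The arrays hold 14692 spots that are not control spots, for 14242 probes. The files give no RNA names. The probe class was read from the letters of each probe ID. There were 1767 TRF probes, read here as tRNA fragment probes because the series is about tRFs and tiRNAs, which are fragments of tRNAs, 9709 MIRNA probes and 2716 PST probes, whose letters are not explained in the sources used here. A further 50 probes, each on 10 spots, carry gene accessions and are called mRNA probes; 46 of these 50 accessions matched a symbol in a RefSeq table of the mouse assembly GRCm38.p6, which was used for symbols alone because the array design names another build. The files do not pair the other IDs with RNA names. None of the 14 miRNA lists fixed beforehand could be matched (0 of 14), so these lists, the tRNA fragment types, the parent tRNA amino acids and the nuclear and mitochondrial parents were not tested.

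Outlier spots were left out, spots of 1 probe were averaged, and log2 of the background-subtracted intensity was taken minus the 75th percentile of each array over all non-control probes, because over 50% of probes were well above background. Probes well above background on at least 3 of 6 arrays were tested, 11793 in all (1761 TRF, 9557 MIRNA, 460 PST and 15 mRNA probes). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Probe classes were tested as sets with camera, with a preset correlation of 0.01 and with an estimated one, and with fry. Values per array were compared with exact two-sided permutation tests, which cannot give a p below 0.1 with 3 samples against 3. A probe not well above background on any array of 1 group has only a bound there. After scaling to the 75th percentile, its fold is given as at least the ratio to the dimmest signal that was well above background. It is left out where that ratio was below 1.

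Probes to be named were set by a rule fixed in advance. Among probes past the threshold whose groups did not overlap, it takes the 6 TRF probes with the largest rise and the 6 with the largest fall, 5 and 5 MIRNA probes, and 3 and 3 probes of the remaining classes. Because the IDs cannot be paired with RNA names, 2 rising and 2 falling TRF IDs are printed and the others of the rule are given as ranges. The mRNA probes are named in addition, which was chosen after their values were seen; 1 tested mRNA probe stays in the counts and is not reported here by itself. Probes were also divided by their mean log2 signal over the 6 arrays before scaling, at 6, 9 and 12; these limits were chosen after seeing the data.

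The fit was tested on simulated data for this comparison with 11712 probes of which 200 were changed. It recovered 76% of changes of 1 on the log2 scale and 94% of changes of 2, and 7 of its 177 calls (3.95%) were false. The simulated noise was independent between probes, with no effect shared by an array, a slide or probes of like signal. Far fewer probes were changed than the 4549 called in the real comparison. These rates therefore leave out errors from the scaling, the slide and correlated probes.

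The alternatives set before the data were examined were quantile normalization, the 75th percentile or the median of probes well above background on all arrays, no filter and a stricter filter on dim probes, the sample number as a block, the slide as a block, another variance prior, another threshold and leaving out each array. Alternatives added after seeing the data were no scaling, no scaling with the variance of each probe alone (ordinary t-tests), scaling on bright probes, normexp correction of the median intensities and slide 1 alone. The arrays lie on 2 slides. Slide 1 holds the 3 control arrays and DNCB 3, and slide 2 holds DNCB 5 and DNCB 6. The number of arrays limits the precision.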

Results

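The comparison asked which small RNAs, tRNA-derived fragments in particular, differ between DNCB-treated and vehicle-treated dorsal skin of BALB/c mice. Treated animals received 1% DNCB in acetone and olive oil (4 to 1) on the back in 4 applications between days 1 and 10, and 0.5% DNCB in 5 applications between days 15 and 27. Controls received the solvent mixture. Each group had 3 arrays. On the control arrays 11857 ± 59.4 probes (SD, n = 3) were well above background, against 11225 ± 124 on the DNCB arrays, with no overlap between groups (exact permutation p = 0.1, the smallest that 3 against 3 allows). No spot was saturated. Pearson's r across probes, which are not independent replicates, was 0.997 between control arrays, 0.989 to 0.992 between DNCB arrays and 0.946 to 0.968 between groups.

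The groups differed in their signal before any scaling. The median intensity of TRF probes was 259 ± 45.4 on control and 108 ± 13.7 on DNCB arrays (SD, n = 3, exact permutation p = 0.1), and that of MIRNA probes was 45.3 ± 6.92 against 18.4 ± 1.30 (n = 3, exact permutation p = 0.1). The intensity summed over all TRF probes, to which bright probes add most, was on average 0.974 times as high on DNCB as on control arrays, a difference below the spread between replicates (n = 3, exact permutation p = 0.8). For MIRNA probes this ratio was 0.805 (n = 3, exact permutation p = 0.2). The directions below depend on the scaling.

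**Figure D1:**
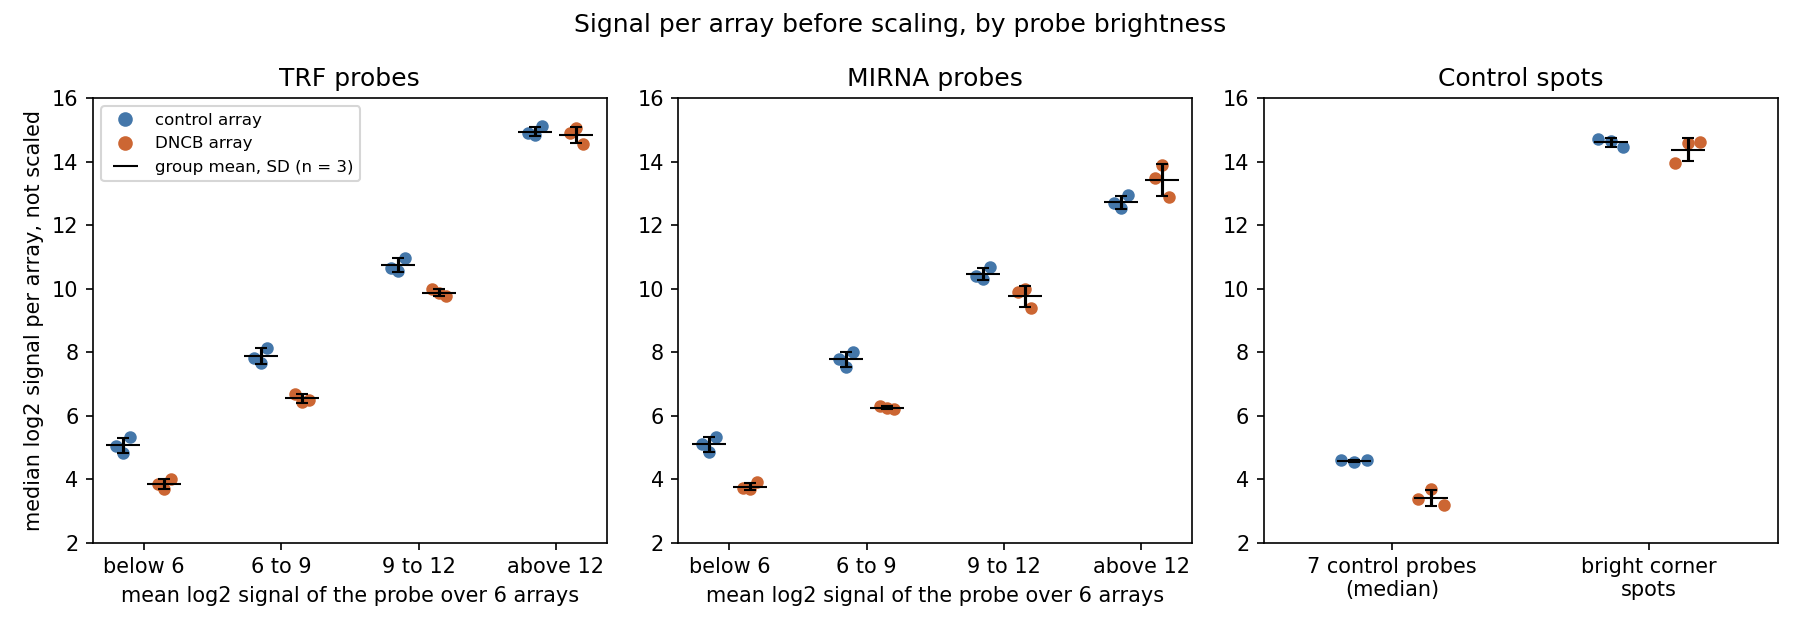
Median log2 intensity per array before scaling (vertical axis) for TRF probes, MIRNA probes and control spots, with probes divided by their mean log2 signal (horizontal axis); points are arrays and black bars are group means with SD (n = 3). Dim TRF probes (below 6) had a mean of 5.06 on control and 3.85 on DNCB arrays, while bright ones (above 12) had 14.94 and 14.83.

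Bright tRNA fragment probes were higher in DNCB-treated skin relative to the bulk of the array. Of 1761 tested TRF probes, 780 rose and 231 fell (limma, adjusted p below 0.05), and 750 did not pass; adjusted over the list alone the counts were 808 and 288. At least 2-fold changes were seen for 586 of the rising and 23 of the falling probes. The TRF median change was +0.25 on the log2 scale. It was +1.61 for the 456 TRF probes with a mean log2 signal above 12, of which 378 rose and 4 fell, and +0.03 for the 597 below 6. For the 487 from 6 to 9 it was -0.15, with 143 higher and 127 lower. Under 7 scalings or corrections it was negative for these, from -1.64 to -0.15. Groups did not overlap for 69.2% of TRF, 50.7% of MIRNA and 53.8% of all tested probes. These shares follow the signal. For TRF and MIRNA probes they were 49.7% and 40.5% below 6, 71.7% and 76.3% from 6 to 9, 81.9% and 85.3% from 9 to 12, and 85.7% and 79.5% above 12. Chance gives 10% for a single probe, but all probes share the 6 arrays, so that a difference between arrays can separate many at once.

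The sign of the TRF median depended on the scaling. It was -1.20 without scaling and -0.06 after quantile normalization, with 249 higher and 1175 lower, and 519 higher and 548 lower, respectively. In the fit without scaling limma gave all probes the same variance, so that the spread of a single probe does not enter its calls there; with the variance of each probe alone, 200 TRF probes were higher and 1113 lower. The median of TRF probes above 12 was positive under each of 7 scalings or corrections, from +0.13 after quantile normalization to +1.61. Of these 7, bright-probe scaling takes the median of all probes above 12 as no change. Most of those are the TRF probes themselves, so its value (+0.14) is small by construction and adds no support. Without scaling it was +0.17, with 128 probes higher and 121 lower. The sign without scaling depends on the summary, since the median signal of these probes per array differed by -0.11 (exact permutation p = 0.7). Under all 6 scalings of the background-subtracted intensities, 213 TRF probes were called higher and 220 lower. Apart from the 75th percentile of all probes, these scalings shift changes downwards (the median of all probes by -0.04 to -1.49). A fall is therefore mostly kept under them by construction. With normexp correction added, which shifts that median by +0.45, 213 TRF probes were called higher and 175 lower. Slide 2 holds no control array, so that a fit with slide as a block takes the change from slide 1, that is from 1 DNCB array. With this block 722 TRF probes rose and 41 fell. The number of falling TRF probes was 99 without control 3, 97 without control 5 and 102 without control 6.

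The largest rises among TRF probes were those of ASMM10SMR20TRF100001210TV1, by 2.89 on the log2 scale (SE 0.16, 7.39-fold, limma adjusted p = 5.14e-05), and of ASMM10SMR20TRF100000117TV1, by 2.84 (SE 0.27, 7.14-fold, adjusted p = 0.000117). The first had 1 outlier spot on a DNCB array, which left 3 control and 2 DNCB values. The 6 rises selected ran from 2.75 to 2.89, and 6 of 6 were called higher under each of 7 scalings or corrections. Without scaling these 6 rose by 1.30 to 1.46. The largest falls were those of ASMM10SMR20TRF100007846TV1, at -1.59 (SE 0.42, adjusted p = 0.0187), and ASMM10SMR20TRF100007930TV1, at -1.55 (SE 0.37, adjusted p = 0.0119). With slide as a block they were -0.80 and -0.82 and no longer passed (adjusted p = 0.282 and 0.194), and the first did not pass without control 3 or control 5 (adjusted p = 0.0669 and 0.0634). Of the 6 falls selected, 5 ran from -1.59 to -1.33 and were called lower under each of the 7, of which only normexp correction shifts changes upwards. The other was not well above background on any DNCB array, so that no fold is given, and it turned positive after normexp correction (+0.69). Of the 6 falls, 4 lost their call with slide as a block (adjusted p = 0.0822 to 0.282), as did 2 without control 3 and 1 without control 5, and 1 of 6 was called lower under each of the 7 and with the block. With the block the 6 falls were at -1.42 to -0.75, and 6 of 6 rises kept their call.

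**Figure D2:**
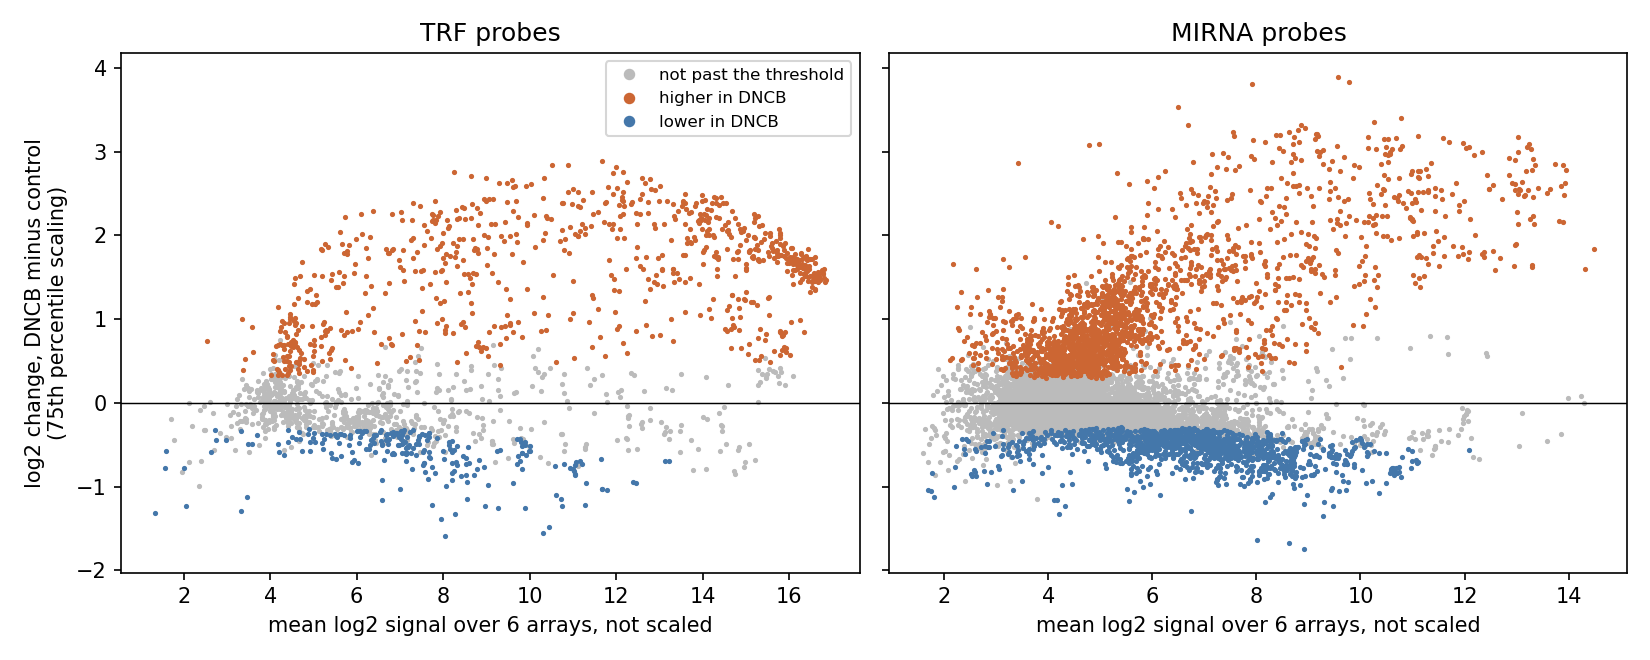
Log2 change between DNCB and control arrays after scaling to the 75th percentile (vertical axis) against mean log2 signal before scaling (horizontal axis); each point is 1 tested TRF or MIRNA probe, orange if higher and blue if lower in DNCB (limma adjusted p below 0.05). The bright end holds mostly rising probes, with 378 of 456 TRF and 65 of 83 MIRNA probes above 12; without scaling 128 and 50 of these were higher.

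MIRNA probes moved in both directions. Of 9557 tested, 1960 rose and 1318 fell (limma), with 1921 and 1243 adjusted over the list alone. The median change was -0.05. It was -0.17 after quantile normalization, with 1700 higher and 2596 lower, -0.23 with scaling to the median, with 1540 and 3190, and +0.41 after normexp correction, with 6659 and 1647. Of the 83 MIRNA probes above 12, 65 rose and 1 fell, with a median of +2.28; without scaling their median was +0.83, with 50 higher and 18 lower. Their median was positive under each of 7 scalings or corrections, from +0.81 to +2.28. Of the 2134 MIRNA probes from 6 to 9, 396 rose and 836 fell, with a median of -0.30. Under the 7 that median was negative throughout, from -1.79 to -0.30. The 5 selected rises ran from 3.41 to 3.89 and the 5 selected falls from -1.74 to -1.32. Called the same way under each of the 7 were 5 of the rises and 4 of the falls. For the falls this is a weak check, since of the 7 only normexp correction shifts changes upwards. Of the 5 falls, 4 lost their call with slide as a block (adjusted p = 0.0794 to 0.222), and 0 of 5 were called lower under each of the 7 and with the block. The 5 falls were at -1.29 to -0.98 there, so that a lost call is not a lost change. With the block 5 of 5 rises kept their call. Without control 3, 2 of the falls lost their call, at -1.56 and -1.49. With slide as a block 1429 MIRNA probes rose and 416 fell. Falling MIRNA probes numbered 585 without control 3, 658 without control 5 and 719 without control 6. Without scaling 329 were higher and 8643 lower.

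Of 460 tested PST probes, 214 rose and 38 fell, with a median change of +0.65; adjusted over the list alone the counts were 222 and 42. Most of them, 391, had a mean log2 signal below 6. The filter on dim probes moved these values. Without it 1799 PST probes rose and the median was +1.17, and with the stricter filter 14 fell and the median was +1.03. The 75th percentile was 121 on control and 43.9 on DNCB arrays. Scaling to it therefore raises a probe at the background on all arrays by construction. The rises without the filter include such probes and do not count as changes of their RNAs. Without scaling the median was -0.80, with 55 higher and 278 lower. Of the 3 selected rises of the remaining classes, all PST, 2 were 2.85 and 3.04 on the log2 scale. The third was not well above background on any control array and was at least 5.57-fold higher. All 3 were called higher under each of the 7 scalings or corrections. The 3 selected falls ran from -1.45 to -1.39, and 0 of 3 were called lower under all 7. All 3 lost their call with slide as a block (adjusted p = 0.0801 to 0.186), where they were at -1.22 to -0.66, and 1 did not pass without control 3. With slide as a block 175 PST probes rose and 12 fell. Falling PST probes numbered 17 without control 3 and 20 without control 5.

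As sets against the other probes, which are mostly dimmer than the TRF probes, the TRF probes ranked higher (camera adjusted p = 2.07e-05), the MIRNA probes lower (adjusted p = 1.12e-06) and the PST probes higher (adjusted p = 1.10e-06), while the mRNA probes did not pass (adjusted p = 0.542). The mRNA set did pass without a filter on dim probes, with the stricter filter and without DNCB 6 (camera adjusted p = 6.65e-06, 0.0326 and 0.0233). Without the filter the set includes probes at the background, which the scaling raises on DNCB arrays by construction. With an estimated correlation, only the MIRNA call held (adjusted p = 0.00577), and the TRF and PST calls did not (adjusted p = 0.565 for both). The MIRNA set holds most of the probes (9536), so its call is largely the other side of the TRF and PST calls. Its test allows for the correlation among MIRNA probes alone (0.00376), not for that among TRF (0.131) or PST probes (0.407). It is therefore no separate evidence of a MIRNA fall. The MIRNA call turned sign and was lost after normexp correction (adjusted p = 0.877), the TRF call was lost after quantile normalization (adjusted p = 0.269), and it turned sign after normexp correction (adjusted p = 0.0987). The fry test, which asks whether the probes of a set move on balance one way, gave a rise for TRF (adjusted p = 0.00631), MIRNA (adjusted p = 0.00648) and PST probes (adjusted p = 0.0259) but not for mRNA probes (adjusted p = 0.302). For MIRNA probes the tests differ in sign, as do the median of -0.05 and the mean per array, which was 0.12 higher in DNCB (exact permutation p = 0.1). Before scaling the MIRNA mean differed by -1.33. The TRF mean per array was 0.55 higher after scaling and differed by -0.90 before it, and the PST mean was 0.67 higher and differed by -0.78 (each exact permutation p = 0.1). Set directly against each other, the median signals of TRF and MIRNA probes moved apart by 0.03 (exact permutation p = 0.9). Within the same range of signals the TRF change lay above the MIRNA change by 0.13 below 6 and by 0.20 from 6 to 9, and under it by 0.14 from 9 to 12 and by 0.80 above 12 (exact permutation p = 0.1, 0.1, 0.4 and 0.1), although above 12 TRF probes are the brighter. On slide 1 the TRF median was +0.36, the MIRNA median -0.03 and the PST median +0.82, and a fit with slide as a block gives these values by construction.

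Over all 11793 tested probes, 2958 rose and 1591 fell, so that 65.0% of calls were higher. That share was 42.8% after quantile normalization, 39.7% when arrays were scaled to the median of well-measured probes, 5.90% without scaling, 5.25% with bright-probe scaling and 79.7% after normexp correction of the median intensities. With slide as a block 2330 rose and 469 fell (83.2% higher). The falling probes numbered 703 without control 3, 777 without control 5 and 852 without control 6. Under all 6 scalings of the background-subtracted intensities, 555 probes were called higher and 1537 lower. Falls are mostly kept there by construction. All 1591 were still called lower with scaling to the median, without scaling and with bright-probe scaling. With normexp correction added, 555 were still called higher, but 1162 lower.

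The mRNA probes gave low signals. Of 15 tested, 4 rose, 4 fell and 7 did not pass (limma); adjusted over the list alone the counts were 5 and 4. Apoe, which encodes the lipid carrier apolipoprotein E, rose by 1.30 on the log2 scale (SE 0.13, 2.47-fold, adjusted p = 0.000158), and Rps4l, related to a ribosomal protein gene, by 1.36 (SE 0.18, 2.57-fold, adjusted p = 0.000678). A probe whose accession matched no symbol rose by 1.097 (adjusted p = 0.00185). Without scaling these 3 differed by -0.15, -0.09 and -0.35. Lhx1, a homeobox gene, passed as higher (adjusted p = 0.0465) but was not well above background on any DNCB array, so that no fold is given. It lay at -0.73 without scaling. It did not pass after quantile normalization, without a filter or with a trend and robust prior (adjusted p = 0.094, 0.0591 and 0.080), with scaling to the median, nor without control 3, 5 or 6 or DNCB 3 or 5 (adjusted p = 0.155, 0.0832, 0.103, 0.128 and 0.107).

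Of the 4 mRNA probes that fell, 3 are described here. Prdx2, a peroxiredoxin gene, passed as lower (adjusted p = 0.00728), with no fold given because its bound was below 1; with a trend and robust prior it did not pass (adjusted p = 0.0867). Pex11a, a peroxisome gene, was at least 1.32-fold lower (adjusted p = 0.0322) and the olfactory receptor gene Olfr1307 at least 1.25-fold lower (adjusted p = 0.0252). Prdx2, Pex11a and Olfr1307 were not well above background on any DNCB array. None of these 3 falls passed with slide as a block (adjusted p = 0.098, 0.265 and 0.303), and each turned positive after normexp correction (+0.68, +0.54 and +0.56). Pex11a did not pass without control 3 or 5 (adjusted p = 0.104 and 0.108), nor Olfr1307 without control 3, 5 or 6 or DNCB 5 (adjusted p = 0.0737, 0.085, 0.0592 and 0.0651). Among those that did not pass, H2-M2 was at -0.15, Duox1 at +0.11, E2f1 at +0.19, Gamt at +0.46 (adjusted p = 0.0564), Olfr166 at +1.04, H2-Q7 at +1.65 and Gsta4 at +2.26. With 1 array left out at a time, Olfr166 ranged from 0.57 to 1.85, H2-Q7 from 0.79 to 2.93 and Gsta4 from 1.43 to 3.72, lowest without DNCB 3 and highest without DNCB 6, where all 3 passed (adjusted p = 5.97e-05, 0.00013 and 2.65e-05). The groups overlap for these 3. Gamt passed under several alternatives, among them the trend and robust prior (adjusted p = 0.0304) and without DNCB 6 (adjusted p = 0.00464), and was at -0.99 without scaling. Without DNCB 6, 9 mRNA probes rose, and without control 3 or control 5, 2 fell.

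**Figure D3:**
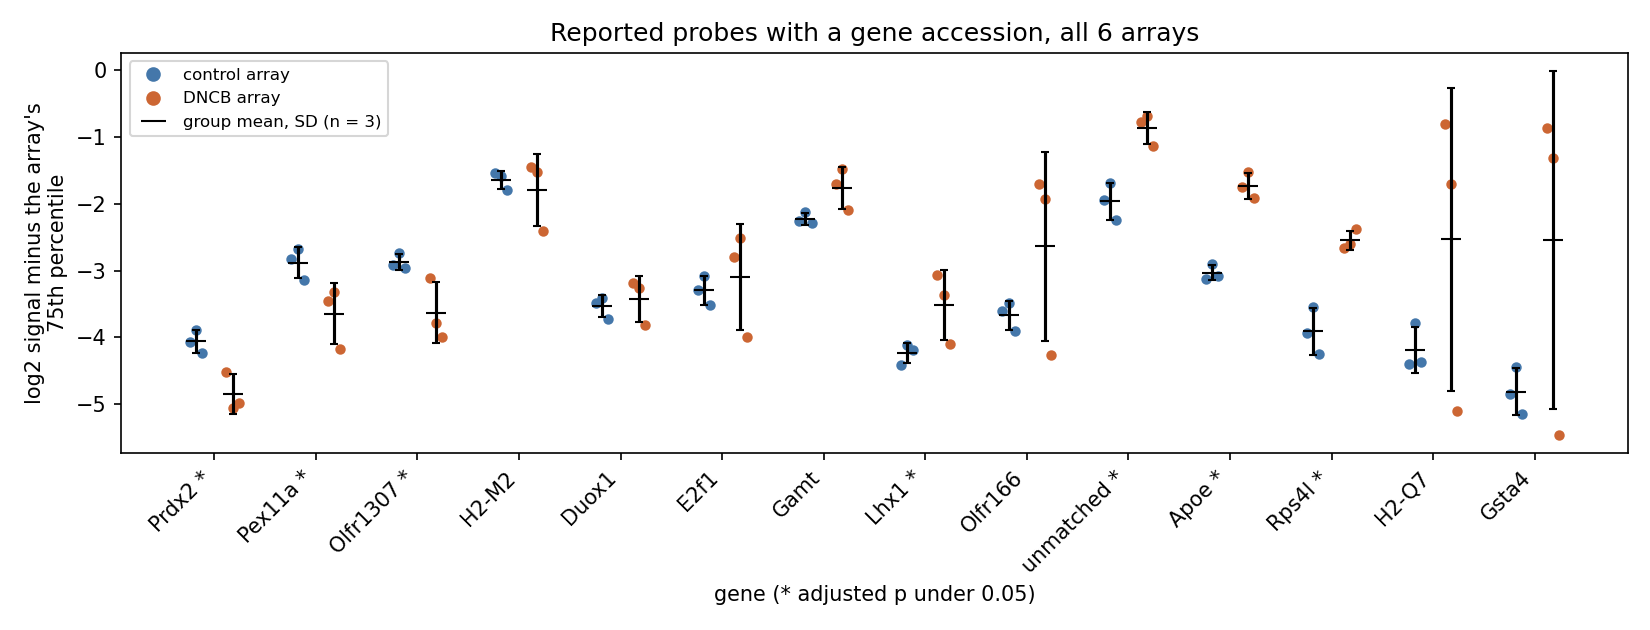
Log2 intensity minus the array's 75th percentile (vertical axis) for 14 of the 15 tested mRNA probes (horizontal axis), with points for the 6 arrays and black bars for group means with SD (n = 3). Apoe and Rps4l lie higher on the 3 DNCB arrays than on the 3 control arrays, which holds after this scaling but not without scaling, where they differed by -0.15 and -0.09; DNCB 6 is the lowest DNCB array for 12 of the 14 probes shown, by most for Gsta4, H2-Q7 and Olfr166.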

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

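No scaling, no scaling with the variance of each probe alone, bright-probe scaling, normexp and slide 1 alone were chosen after seeing the data; the other alternatives were planned, and of these normexp on mean intensities was not run, because the files hold no such column. Over 69 results and 1293 values under alternatives, 1031 kept their direction and their side of the threshold or size, and 70 reversed. Those kept include changes that the sample number as a block and the trend and robust prior leave the same by construction. Of the 70 that reversed, 42 did so without scaling or with bright-probe scaling and 11 with normexp. These settings move the level taken as no change: relative to the 75th percentile, the median of all probes shifted by -1.45 without scaling, -1.49 with bright-probe scaling, -0.12 with quantile normalization, -0.18 with scaling to the median and +0.45 with normexp. Low signal over background limits the dim probes. Apart from the shifts that these constructions give, the cause was not tested. Set tests that crossed the threshold are given by setting here. Single probes lost their call most often with slide as a block (14 lost), which estimates the change from slide 1 and so from 1 DNCB array. With the trend and robust prior, Prdx2 and Lhx1 did not pass (adjusted p = 0.0867 and 0.080), while Gamt did (adjusted p = 0.0304). Gamt also passed with the 75th percentile of well-measured probes (adjusted p = 0.0457), the stricter filter (0.0463), normexp (0.000272) and without DNCB 6 (0.00464).

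After quantile normalization 3216 probes fell, 519 TRF probes rose and 548 fell, and 2596 MIRNA and 68 PST probes fell. The medians there were -0.061 for TRF and -0.17 for MIRNA probes, -0.10 for TRF probes below 6 and -0.00486 for those of 9 to 12; the TRF set test had adjusted p = 0.269 and Duox1 was at -0.055. With the 75th percentile of probes well above background on all arrays, the MIRNA median was -0.093 and that of TRF probes below 6 was -0.013. Scaled to the median of those probes, 3733 probes fell, of them 480 TRF, 3190 MIRNA and 59 PST; medians were +0.065 for TRF, -0.23 for MIRNA and -0.15 for TRF probes below 6, and Duox1 was at -0.069. With the estimated correlation the TRF and PST sets both had adjusted p = 0.565.

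Without scaling 634 probes were higher and 10105 lower, with 249 and 1175 TRF, 329 and 8643 MIRNA, 55 and 278 PST, and 1 and 9 mRNA probes. Medians were -1.20 for TRF, -1.50 for MIRNA, -0.80 for PST and -0.99 for mRNA probes, -1.42 for TRF probes below 6, -0.67 for TRF and -0.65 for MIRNA probes of 9 to 12. In this fit limma gave all probes the same variance. With the variance of each probe alone the changes are identical by construction, and 429 probes were higher and 9796 lower, with 200 and 1113 TRF, 203 and 8447 MIRNA, 26 and 227 PST, and 0 and 9 mRNA probes; the call of Gsta4 (adjusted p = 0.000397) was lost (adjusted p = 0.613). Single genes that reversed were E2f1 at -1.26, Apoe at -0.15, the unmatched probe A_51_P237746 at -0.35, Olfr166 at -0.41, Rps4l at -0.088, Lhx1 at -0.73, Duox1 at -1.34 and Gamt at -0.99. With bright-probe scaling 559 probes were higher and 10093 lower, with 216 and 1174 TRF, 296 and 8631 MIRNA, 47 and 279 PST, and 0 and 9 mRNA probes (limma). Medians were -1.24 for TRF, -1.54 for MIRNA, -0.84 for PST and -1.03 for mRNA probes, -1.46 for TRF probes below 6, -0.71 for TRF and -0.69 for MIRNA probes of 9 to 12. E2f1 was at -1.30, Apoe at -0.19, A_51_P237746 at -0.40, Olfr166 at -0.46, Rps4l at -0.13, Lhx1 at -0.77, Duox1 at -1.38 and Gamt at -1.03.

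With normexp on median intensities 8162 probes rose, 420 TRF probes fell, 6659 MIRNA, 419 PST and 15 mRNA probes rose, and 14 PST and 0 mRNA probes fell. Medians were +0.44 for TRF, +0.41 for MIRNA and +0.47 for MIRNA probes below 6. The TRF and MIRNA set tests turned sign (adjusted p = 0.0987 and 0.877). Reversed were 1 selected TRF probe at +0.69, 1 MIRNA probe at +0.11, 1 PST probe at +0.38, and Prdx2 at +0.68, H2-M2 at +0.35, Olfr1307 at +0.56 and Pex11a at +0.54.

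Without a filter on dim probes 4553 probes, 1799 PST and 32 mRNA probes rose. Medians were +1.17 for PST and +1.36 for mRNA probes, and the mRNA set passed (adjusted p = 6.65e-06). These values include probes at the background, which the scaling raises on DNCB arrays by construction. With probes well above background on all 6 arrays, 14 PST and 0 mRNA probes fell, medians were +1.03 for PST and +1.097 for mRNA probes, and the mRNA set passed (adjusted p = 0.0326). With slide as a block 469 probes fell, of them 41 TRF, 416 MIRNA, 12 PST and 0 mRNA; the TRF median was +0.36, that of MIRNA probes below 6 was 0.00815, and H2-M2 was at +0.20. On slide 1 alone 8 mRNA probes rose, the TRF median was +0.36, that of MIRNA probes below 6 was 0.00815, H2-M2 was at +0.20, and the mRNA set had adjusted p = 0.0369. With 1 DNCB array the spread between DNCB arrays is not measured there, so that these p-values and calls support no result. At an unadjusted p below 0.05 with a change of at least 1.5-fold, 649 probes fell, 116 of them TRF.

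Leaving out each array in turn gave 2382 to 3229 rising and 703 to 2061 falling probes, 695 to 811 and 97 to 306 TRF, 1504 to 2128 and 585 to 1770 MIRNA, 176 to 281 and 17 to 53 PST, and 3 to 9 and 2 to 4 mRNA probes. The MIRNA median ranged from -0.074 to -0.023, that of MIRNA probes below 6 from -0.037 to 0.026, and that of TRF probes below 6 from -0.00222 to 0.087. The mRNA set had adjusted p from 0.0233 to 0.998. Gsta4 ranged from 1.43 to 3.72, H2-Q7 from 0.79 to 2.93 and Olfr166 from 0.57 to 1.85, and without DNCB 6 these 3 passed (adjusted p = 2.65e-05, 0.00013 and 5.97e-05). Duox1 ranged from -0.00628 to +0.31, E2f1 from -0.10 to +0.64 and H2-M2 from -0.33 to +0.16.

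The sample numbers are shared between groups. With the number as a replicate block 2956 probes rose and 1494 fell, 775 and 230 of them TRF, and Gsta4 and Gamt passed (adjusted p = 0.0393 and 0.0332). Deviations of same-numbered samples from their group means correlated across probes at r = 0.05, 0.29 and 0.22 for numbers 3, 5 and 6, and control 3 correlated best with DNCB 6, so the numbers were not taken to pair the samples. The block reversed no value. Each number occurs once in each group, so that changes of probes measured on all arrays stay the same by construction and could not reverse.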

Other observations

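The tests of the unscaled signal and of several probes per RNA were chosen after the patterns were seen; the splits and the test of position were set before their results were seen.

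For Gsta4, a glutathione transferase gene, intensities were 4.25, 4.64 and 3.97 on control 3, 5 and 6 and 23.5, 17.1 and 1.06 on DNCB 3, 5 and 6. For H2-Q7, a class I histocompatibility gene, they were 5.80, 7.33 and 6.74 on the control and 24.5, 13.1 and 1.36 on the DNCB arrays. For Olfr166, an olfactory receptor gene, they were 10.0, 9.02 and 9.29 on the control and 13.2, 11.1 and 2.43 on the DNCB arrays. None of these 3 passed with all arrays after scaling to the 75th percentile, and all 3 passed without DNCB 6 (limma adjusted p = 2.65e-05, 0.00013 and 5.97e-05) and after normexp correction on all arrays (adjusted p = 0.000378, 0.000528 and 0.000271). Normexp correction called all 15 tested mRNA probes higher, so that passing there does not set these 3 apart. Gsta4 also passed with the sample number as a block (adjusted p = 0.0393); its call without scaling (adjusted p = 0.000397) came from a variance shared by all probes and was lost with its own variance (adjusted p = 0.613) and with bright-probe scaling (adjusted p = 0.118). The groups overlap for all 3. DNCB 6 differs from the other DNCB arrays beyond these genes. It was the lowest DNCB array for 13 of 15 tested mRNA probes. On it 10% of mRNA and 10.4% of PST probes were well above background, against 22% of mRNA and 14.3% and 14.1% of PST probes on DNCB 3 and 5. By the share of probes well above background it was not low for the other classes. On it 98.0% of TRF and 95.3% of MIRNA probes were well above background, against 97.8% and 94.2% of TRF and 94.7% and 93.0% of MIRNA probes on DNCB 3 and 5. Before scaling, its median log2 signal was the lowest of the DNCB arrays for TRF and MIRNA probes above 12. It was 14.55 and 12.88 there, against 14.89 and 13.49 on DNCB 3 and 15.06 and 13.88 on DNCB 5. For TRF and MIRNA probes below 6 it was the highest of the DNCB arrays, at 4.01 and 3.89.

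Before scaling, the median log2 signals of TRF and MIRNA probes were lower on DNCB arrays in each range below 12. They differed by -1.21 and -1.34 below 6, -1.33 and -1.53 from 6 to 9, and -0.86 and -0.71 from 9 to 12. Above 12 they were level or higher. The distance between TRF probes above 12 and below 6, which scaling a whole array cannot change, grew by 1.098 on the log2 scale (9.88 ± 0.118 on control and 10.98 ± 0.417 on DNCB arrays, SD, n = 3, exact permutation p = 0.1). Lower scanner or hybridization sensitivity that acts alike at all signal levels is argued against as the whole source. It leaves distances on the log2 scale unchanged, while that between TRF probes above 12 and those of 6 to 9 grew by 1.22 (7.08 ± 0.112 on control and 8.29 ± 0.295 on DNCB arrays, SD, n = 3). A loss that depends on the signal level stays open. The bright corner spots, tested first, lie in the bright range and do not decide it. Their difference of -0.23 rests on DNCB 3 (-0.66) and was -0.012 without that array. Lower nonspecific signal on DNCB arrays is a candidate explanation for the probes below 6. Apart from the bright corner spots, 7 control probes were well above background on all 6 arrays. They have no named mouse target and were lower on the DNCB arrays, with a change of -1.17. Their median log2 signal on control arrays was 4.58, against 7.77 for MIRNA probes from 6 to 9. A loss of as many intensity units as in these control probes is too small for the fall of those MIRNA probes. Of the 7, 6 have IDs of the same stem and may not be independent. The 14 probes taken first, by the control arrays alone, gave -1.04. The negative control spots were not well above background on any array (mean 1.01 on control and 1.02 on DNCB arrays), so that they could not show a fall. Among other control probes not well above background, the larger changes were mostly falls, such as (+)E1A_r60_3 (-1.87), ETG10_234183 (-1.38), ETG02_36680 (-1.20) and (+)E1A_r60_1 (-1.10). ETG10_13482 (+1.45) and DCP_1_11 (+0.88, groups overlapping) went the other way. The sources used here do not say whether spike-in RNA was added for the 7 probes. The slide stays open because 1 DNCB array shares a slide with the controls; on that array dim MIRNA probes differed from the controls by -1.39. The DNCB treatment itself stays open and was not tested, and values of RNA quality were not used here.

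MIRNA probes with neighbouring ID numbers changed alike. The correlation of log2 changes across probes, which are not independent replicates, was 0.749 at a number distance of 1 and lay between 0.304 and 0.313 at distances of 5 to 12. For TRF probes, whose numbers lie farther apart, it was 0.472 at a distance of 4, -0.081 at 6, 0.103 at 8, -0.599 at 10 and -0.069 at 12. For MIRNA probes this is consistent with several probes per RNA, in which case counts of probes overstate the number of RNAs; the same caution applies to TRF counts. Position on the array is argued against, since over the pairs farthest apart the correlation at a distance of 1 was 0.756. No biological explanation was tested for this pattern.

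The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share of splits under 0.05. The real split called 4549 probes, 1011 TRF, 3278 MIRNA, 252 PST and 8 mRNA probes, and the highest count of any other split was 0 for each; 1 of the 10 splits, the real one, gave as many. For the set tests with a preset correlation, the real split called 3 of the 4 classes and another split called 4; 5 of the 10 splits called as many as the real one.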
